A study of Rattus norvegicus with 4 samples.

How the data were processed

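Gene expression was measured by RNA sequencing in rat tendon stem/progenitor cells (TSPCs), fibroblast-like progenitors grown out of tendon. The 4 libraries formed 2 groups of 2: cells given DMSO, the solvent control, and cells given U0126, an inhibitor of the MEK kinases that phosphorylate ERK. Groups and replicate numbers were taken from the sample labels. The labels number the libraries as biological replicates without saying which animal, culture or day each came from, so p-values measure only the spread between these libraries. Dose, exposure time, the aligner, the counting tool, its strand setting and the annotation release are not given in the sources used here. RNA was extracted with Trizol and libraries followed a standard Illumina protocol, per the labels' protocols. The rat genome build rn6 is named in the submitters' processing notes.

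The authors deposited 1 table of 32623 Ensembl gene identifiers with symbols, positions and functional annotation. Per the file headers, the deposited table holds a count, a TPM and an FPKM value per gene for every library. The deposited counts were whole numbers, not normalized, and summed to between 36888913 and 42785190 per library. The deposited TPM values, which scale each library to one fixed total, were not used in any test. The deposited FPKM values, which scale fragments by gene length and library size, were used only to derive an effective length per gene for a check of length bias. Columns were matched to samples by the letter and number that their headers share with the sample descriptions, and 0 columns were left unmatched. All rows named a gene identifier. Positions are given as deposited. Whether the counting divided reads among overlapping or near-identical genes is unknown. The 2 annotated copies of the collagen type I alpha 2 gene on chromosome 4 are a case in point, and values for either copy are uncertain.

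From the counts, 14023 genes passed edgeR's filterByExpr at its defaults (a minimum count of 10 and a minimum total of 15). Library sizes were scaled by TMM, and U0126 was compared with control by edgeR's quasi-likelihood F test (glmQLFit and glmQLFTest, two-sided), with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Log2 fold changes carry edgeR's prior count of 0.125. Their standard error was taken as the absolute log2 fold change divided by the square root of the F statistic. Levels are TMM-scaled CPM, counts scaled to library size, as mean ± SD over the 2 libraries of a group. A group with 0 counts was given a floor of 3 counts over its 2 libraries, and folds against it are lower bounds. A single library with 0 counts allows up to between 0.0701 and 0.0813 CPM. Intervals and floors cover counting error only.

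Before the data were examined, 28 gene lists with 524 members were fixed. They covered the ERK pathway, tendon and neighbouring lineages, matrix, cell cycle, metabolism, stress, and markers of other cell types that a tendon culture could hold. The table held 515 of the members, and 446 distinct genes were tested. Members not found under their symbol or a fixed alternative symbol were left out of the list tests. Each list was tested with camera on the edgeR fit with a preset inter-gene correlation of 0.01, adjusted over the 28 lists. Camera with a correlation estimated from the data and fry were run as alternatives. The estimated version has 2 residual degrees of freedom here and called 0 lists at an adjusted p under 0.05, while 4 lists had an unadjusted p under 0.05, and fry called 16. Fry tests whether a list's genes move on balance in one direction and does not compare them with other genes.

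The genes named in the text were also set by a rule fixed beforehand. They were the 8 genes with the largest change in each direction among those past the threshold, with a mean log2 CPM of at least 3 and both U0126 libraries on one side of both controls. To these were added up to 3 members of each list with the smallest adjusted p, or the most abundant tested member where none passed, and 18 genes fixed by name. Placeholder names such as locus numbers were not counted as symbols, a reading of the rule set after the table had been seen. The rule gave 110 genes. Some genes that the rule named are not reported here. A gene named outside it is said to have been chosen after its values were seen.

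The test was tried on simulated counts drawn from the means and dispersions of this comparison, with 200 genes changed. Of 13841 simulated genes tested, it recovered 84% of those changed 2-fold and 100% of those changed 4-fold. The changed genes were drawn only from above a low-expression cut, and were fewer than the 2792 called in the data. Each gene had the same dispersion in both groups. These rates therefore do not cover low-count genes or a difference in spread between the groups. Of its 197 calls, 6.60% fell on genes with no simulated change. Camera called both changed lists and 0 of 100 unchanged ones. Every member of a changed list was simulated as changed 4-fold in the same direction. The 2 calls therefore do not cover lists with small or mixed changes. The simulated genes were drawn independently of one another, while the estimated inter-gene correlation of the mitosis list was 0.832. The list result therefore does not test the preset correlation.

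The 2 control libraries differed from each other beyond sampling noise (chi-square of their counts per degree of freedom, 14.9), as did the 2 U0126 libraries (44.0), so all 4 were kept as separate samples. Alternatives fixed beforehand were DESeq2's size factors (RLE), library totals alone, no filter on low counts, a stricter filter (at least 5 CPM in 2 libraries), DESeq2, limma-voom, the replicate number as a block, and leaving out each library in turn. Leaving out the mitochondrially encoded genes and removing the trend of fold change with effective length were added after the data had been seen.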

Results

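RNA sequencing counts were obtained from rat TSPCs, 2 control libraries given DMSO and 2 libraries given U0126. The comparison asks which transcripts change in these cells when MEK, and through it ERK, is inhibited. Total counts were 38890310 and 42785190 in the controls and 38671289 and 36888913 in the U0126 libraries. Between 16100 and 16329 genes had a count in each library. The first principal component of log2 CPM held 75% of the variance and separated the groups, and the second, with 15.8%, separated the U0126 libraries from each other. Mitochondrially encoded genes took 3.48% and 2.98% of the counts in the controls and 5.64% and 4.82% with U0126. All n below are 2 libraries per group.

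Of 14023 genes tested, 2792 differed between U0126 and control by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With U0126, 1180 were higher and 1612 lower. A change of at least 2-fold was seen in 1127, of which 401 were higher and 726 lower. Among genes with a mean log2 CPM of at least 3 over the 4 libraries, the strongest falls were in Ccl22, Cxcl2 and Ramp3. Ccl22 and Cxcl2 are chemokines, and Ramp3 is a partner of calcitonin-family receptors. Ccl22 (chromosome 19, 10674189 to 10681145, rn6) went from 52.7 ± 22.5 to 0.354 ± 0.202 CPM. Cxcl2 went from 17.5 ± 5.52 to 0.276 ± 0.391 CPM, and Ramp3 from 21.9 ± 3.04 to 0.382 ± 0.242 CPM. The other 5 of the 8 strongest falls were Asf1b, Espl1, Cenpf, Ccnf and Mybl2, genes of chromatin assembly and cell division that were 10.5-fold to 12.2-fold lower. Under the same cut, the strongest rise was in Gdf10, a TGF-beta family ligand (25.4-fold, log2 fold change 4.67 ± 0.47 SE). Next was Adamts15, a matrix protease of the aggrecanase family (19.3-fold, 4.27 ± 0.17). The transcription factor Erg (15-fold), the chemokine Cxcl13 (14.7-fold) and Prima1 (13.9-fold) followed. Ptger3, a prostaglandin E receptor, was 12.3-fold higher, Igfbp3 12.2-fold and Nkd1, a Wnt pathway inhibitor, 12.1-fold. Control levels of these 8 were low, from 0.726 CPM (Gdf10) to 3.75 CPM (Prima1), except Igfbp3 at 40.7 CPM. All but Igfbp3 thus passed the expression cut through the U0126 libraries. The Cxcl2 call was lost under DESeq2 (adjusted p = 0.0590, the largest over its alternatives, which went down to 8.13e-06). Some of these sizes rested on 1 library. Without U0126 replicate 1 the log2 fold change went from 4.67 to 3.91 for Gdf10, below the 4.30 of Adamts15, from 3.91 to 3.15 for Erg, from -3.51 to -4.65 for Cenpf and to -4.98 for Cxcl2, which was 64.0-fold lower with all 4 libraries. Without U0126 replicate 2 it went from -7.21 to -7.95 for Ccl22, from -5.84 to -6.69 for Ramp3 and to -2.90 for Cenpf, and the remaining library had 0 counts of Cxcl2. With limma-voom the log2 fold change of Cxcl2 was -7.66. The U0126 libraries differed more from each other than the controls did. The number of changed genes was 913 without control replicate 1, 899 without control replicate 2, 3277 without U0126 replicate 1 and 4644 without U0126 replicate 2.

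**Figure D1:**
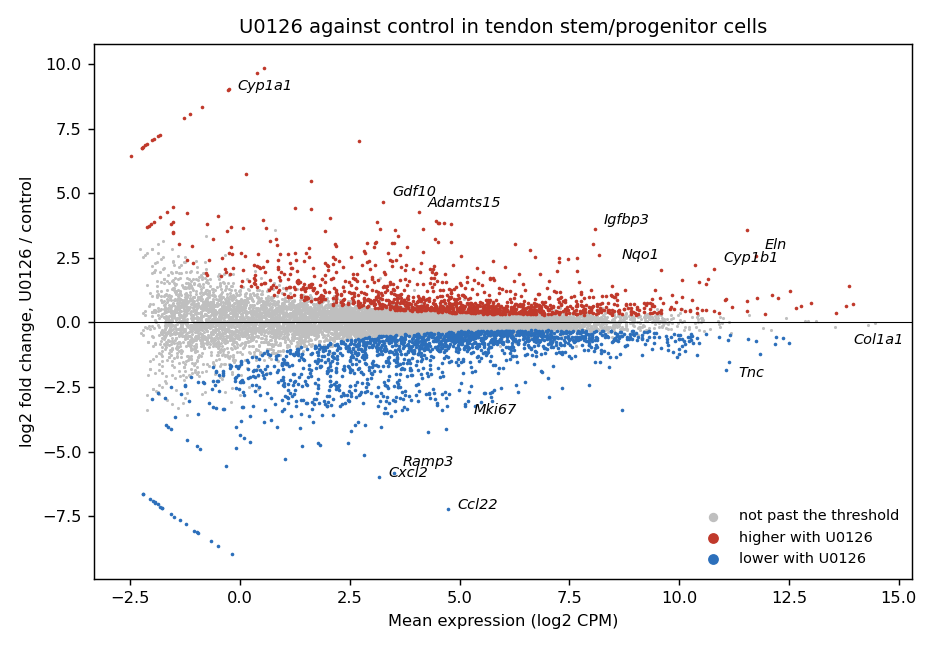
Each point is 1 of 14023 tested genes. The x axis is mean log2 CPM over the 4 libraries and the y axis the log2 fold change of U0126 over control; 1180 genes in red were higher and 1612 in blue lower, and the straight lines of points at the far left are genes with 0 counts in one group, whose fitted folds are not bounds.

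Genes transcribed downstream of ERK were lower with U0126. Of 19 tested ERK pathway output genes, 10 fell, 1 rose and 8 did not pass the test. Dusp5, which encodes a nuclear ERK phosphatase, fell 5.03-fold, and the ETS factors Etv1 and Etv4 fell 5.09-fold and 3.97-fold. Dusp6, the cytoplasmic ERK phosphatase (chromosome 7, 41475163 to 41479392, rn6), went from 37.2 ± 0.188 to 19.8 ± 3.14 CPM (edgeR adjusted p = 0.00418). Cyclin D1 (Ccnd1) fell 1.41-fold, from 352 ± 7.47 to 249.9 ± 1.72 CPM. Spry4 was at 58.5 ± 2.62 and 47.4 ± 4.46 CPM (edgeR adjusted p = 0.0896). The one member that rose was Myc, from 25.7 ± 1.69 to 33.3 ± 0.659 CPM, named after its values were seen (edgeR adjusted p = 0.0497). Myc lost its call in most alternatives, among them RLE factors, DESeq2, and leaving out either control or U0126 replicate 1. The list was lower as a set (camera adjusted p = 6.31e-06; adjusted p = 0.322 with an estimated correlation). Adjusted over the list alone, 11 members fell and 1 rose. The fallen members numbered 5 without control replicate 1, 7 without control replicate 2 and 14 without U0126 replicate 2; the Ccnd1 call was lost without either control (edgeR adjusted p = 0.0842 and 0.112; down to 8.06e-06 over the other alternatives). Spry4 passed, as lower, without U0126 replicate 2 (edgeR adjusted p = 0.0106, against up to 0.471 in other alternatives).

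Among 18 immediate early genes, the rapid-response transcription factors and their kin, 6 fell, 0 rose and 12 did not pass. The nuclear receptors Nr4a3 and Nr4a1 fell 3.72-fold and 2.29-fold, and Srf, the serum response factor, 1.63-fold. Egr1 (chromosome 18, 27657628 to 27661429, rn6) went from 154 ± 11.7 to 82.7 ± 33.7 CPM, with an edgeR adjusted p of 0.0428. The list was lower as a set (camera adjusted p = 5.37e-04; adjusted p = 0.441 with an estimated correlation), and 7 fell when adjusted over the list alone. Without either control 3 members fell, and without U0126 replicate 2, 15 did. Egr1 lost its call without control replicate 1 or 2 (edgeR adjusted p = 0.131 and 0.210) and under DESeq2, and Srf without control replicate 1 (edgeR adjusted p = 0.0634). Over all alternatives the adjusted p, by edgeR, DESeq2 or limma, lay between 1.45e-05 and 0.210 for Egr1 and between 4.29e-07 and 0.0634 for Srf.

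Transcripts of the pathway's own components showed small differences. Of 19 tested, 2 rose and 3 fell, also when adjusted over the list alone, and the list was not called (camera adjusted p = 0.938). Map2k1, which encodes a MEK kinase targeted by the inhibitor, fell 1.28-fold (111 ± 0.818 to 86.9 ± 2.22 CPM) and Mapk3, an ERK kinase gene, 1.24-fold (245 ± 7.61 to 197 ± 9.41 CPM). Hras, named after its values were seen, fell 1.29-fold. Mapk7 rose 1.61-fold and Pdgfrb, the PDGF receptor beta chain, 1.38-fold. Map2k2 (log2 fold change -0.22 ± 0.11) did not pass. None of the 5 called members, with control replicate 1 or 2 left out, passed edgeR's test, and Map2k2 passed, as lower, without U0126 replicate 2 (edgeR adjusted p = 0.0116), where 5 members fell. The Mapk3 call (edgeR adjusted p = 0.0495) was also lost without U0126 replicate 1 (0.0621) and in several alternatives that kept all 4 libraries, over a range of 0.0121 to 0.341.

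All 24 tested mitosis genes and all 24 tested DNA replication genes were lower with U0126, with median log2 fold changes of -2.79 and -1.72. Mki67, the proliferation antigen (chromosome 1, 207993895 to 208020454, rn6), went from 62.3 ± 3.04 to 7.02 ± 2.94 CPM. The mitotic kinase Plk1 fell 9.50-fold, cyclin B1 (Ccnb1) 8.73-fold and the cytokinesis scaffold Anln 8.25-fold. Rrm2, a subunit of ribonucleotide reductase, fell 9.41-fold, the replicative helicase subunit Mcm5 7.91-fold and Uhrf1, a maintenance methylation factor, 6.41-fold. Both lists were lower as sets (camera adjusted p = 2.64e-66 and 3.10e-43; adjusted p = 0.322 with an estimated correlation for both). All 48 calls also held when adjusted over each list alone. The mitosis count was 24 without any one library, and the replication count was 20 and 19 without control replicate 1 and 2. Among 14 tested p53 targets, 5 rose, including the cell cycle inhibitor Cdkn1a (1.63-fold), the death receptor Fas (2.31-fold) and Tp53inp1 (2.24-fold), and 1 fell, Pmaip1, named after its values were seen. Ccng1 and Mdm2, also named after their values were seen, were the other risers, and 5 rose and 1 fell when adjusted over the list alone. The p53 list was near the threshold (camera adjusted p = 0.0450; adjusted p = 0.322 with an estimated correlation) and was not called without control replicate 1 (camera adjusted p = 0.0650) or U0126 replicate 2 (0.0983). It held 2 higher and 0 lower genes without control replicate 1 or 2, with Cdkn1a at edgeR adjusted p = 0.0718 without control replicate 2 and Tp53inp1 at 0.104 without control replicate 1.

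Part of the tendon lineage genes rose. Of 18 tested, 8 rose, 1 fell and 9 did not pass. Comp, cartilage oligomeric matrix protein (chromosome 16, 20798437 to 20807070, rn6), rose 8.42-fold from 1.57 ± 0.152 to 13.3 ± 4.41 CPM. Aspn, the small leucine-rich proteoglycan asporin, rose 7.01-fold from 24.3 ± 3.82 to 170 ± 51.2 CPM. Scx, the tendon transcription factor scleraxis (chromosome 7, 117519075 to 117521093, rn6), rose 1.70-fold from 12 ± 0.262 to 20.4 ± 0.0321 CPM. Mkx, the tendon homeobox factor, was at 1.36 ± 0.361 and 2.95 ± 0.708 CPM (edgeR adjusted p = 0.0515). Tnc, the matrix glycoprotein tenascin C, was the member that fell, 2.91-fold from 3334 ± 322 to 1144 ± 146 CPM. Col1a1, the main tendon collagen chain, was at 22420 ± 1905 and 22230 ± 2416 CPM (log2 fold change -0.01 ± 0.11 SE). The 2 annotated copies of the alpha 2 chain did not pass either (log2 fold change 0.07 each). They carry a placeholder name, are not among the 18 and were named after their values were seen. Tnmd, a marker of mature tendon cells, had 7 counts over the controls and 2 over the U0126 libraries and was not tested (ratio 0.321, 95% exact Poisson interval 0.0325 to 1.68). The list was higher as a set (camera adjusted p = 3.33e-04; adjusted p = 0.322 with an estimated correlation), and 9 rose and 1 fell when adjusted over the list alone. Without control replicate 1 or 2 the risen members were 5 and 4, and the Scx call was lost (edgeR adjusted p = 0.0715 and 0.0893; down to 7.42e-05 over the other alternatives). Mkx passed without U0126 replicate 1 (edgeR adjusted p = 0.0172, against up to 0.330 in other alternatives) and with the length trend removed.

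**Figure D2:**
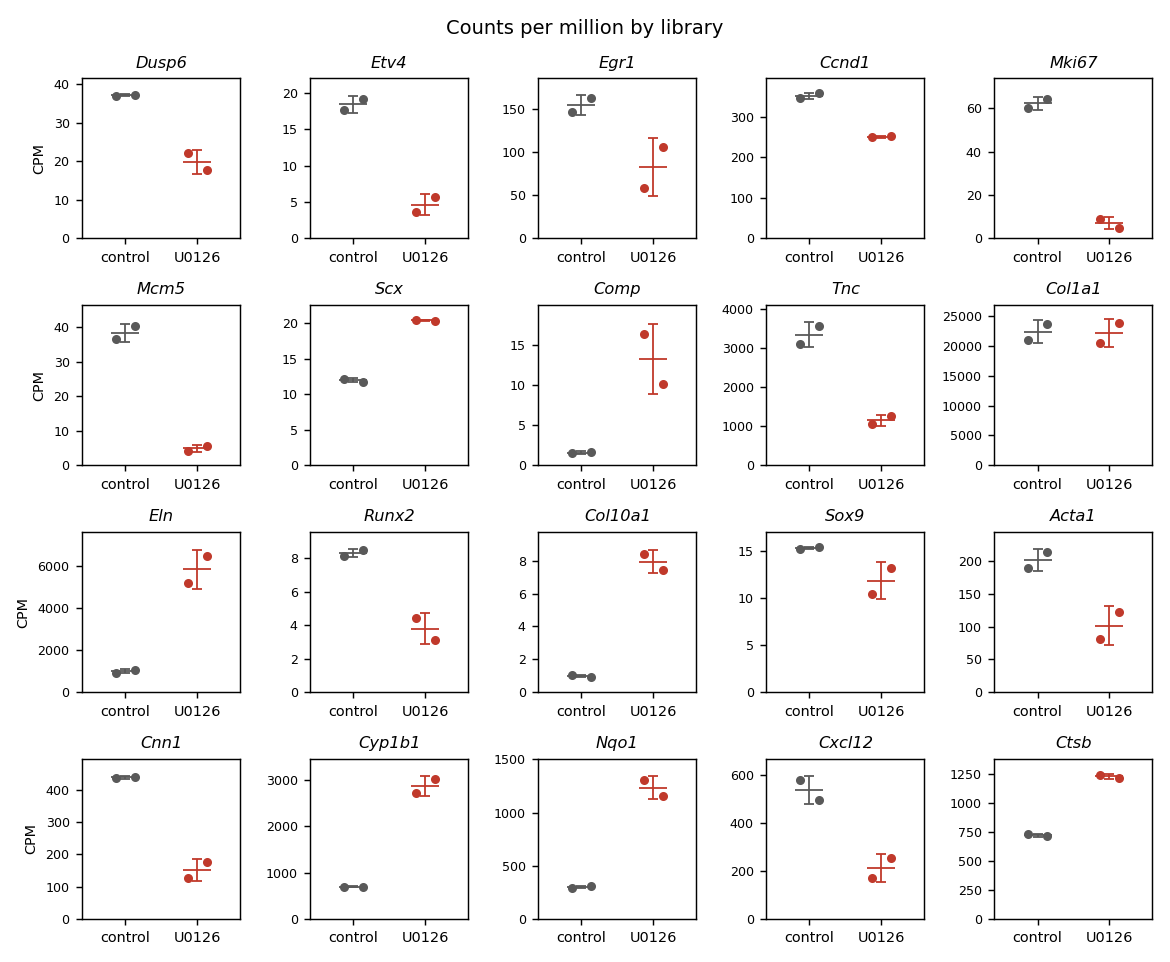
Scaled counts (CPM, y axes starting at 0) of 20 named genes in each control (grey) and U0126 (red) library. Points are libraries, the horizontal bar is the group mean and the whiskers are ± 1 SD over 2 libraries; the 2 groups do not overlap for Scx (means 12 and 20.4 CPM) and overlap for Col1a1 (22420 and 22230 CPM).

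Several cartilage genes rose as well. Of 12 tested, 7 rose, 1 fell and 4 did not pass, also when adjusted over the list alone. Col10a1, the hypertrophic cartilage collagen, rose 8.13-fold but stayed low (0.975 ± 0.0472 to 7.95 ± 0.692 CPM). Col9a2 rose 5.59-fold (46.5 ± 1.19 to 259.6 ± 75.6 CPM) and Col11a1 3.14-fold (519 ± 72.2 to 1626 ± 322 CPM). Sox9, the chondrogenic transcription factor, did not pass (log2 fold change -0.37 ± 0.16 SE). Acan, the large cartilage proteoglycan, was the member that fell, from 1915 ± 165 to 791 ± 149 CPM, and was named after its values were seen. The list was higher as a set (camera adjusted p = 1.74e-04; adjusted p = 0.322 with an estimated correlation). The risers numbered 4 without control replicate 1 or 2 and 3 under the stricter filter; Sox9 passed, as lower, without U0126 replicate 2 (edgeR adjusted p = 0.0128) and in none of its other alternatives, where it reached 0.472.

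Bone and fat genes went both ways. Of 10 tested bone genes, 2 rose and 3 fell, with or without adjustment over the list alone. Alpl, alkaline phosphatase, rose 3.03-fold and Ibsp, bone sialoprotein, 2.22-fold. The homeobox factor Msx2 fell 7.29-fold, and Runx2, the osteoblast master regulator, 2.20-fold from 8.32 ± 0.252 to 3.78 ± 0.925 CPM. Phex, named after its values were seen, fell 3.99-fold. The list was not called (camera adjusted p = 0.852). The Runx2 call was lost without control replicate 1 or 2 (edgeR adjusted p = 0.0771 and 0.0951), and that of Ibsp without control replicate 2 (0.0576), where 1 bone gene rose and 1 fell; 2 rose and 1 fell without control replicate 1. Over all alternatives the adjusted p, by edgeR, DESeq2 or limma, lay between 4.19e-04 and 0.0951 for Runx2 and between 7.26e-06 and 0.0576 for Ibsp. Of 9 tested fat genes, 2 rose (Cfd 4.94-fold at under 1 CPM, and Dgat2 1.53-fold) and 1 fell (Scd 1.53-fold). Adjusted over the list alone, 3 rose and 1 fell. Pparg, the adipocyte regulator, was at 8.24 ± 1.70 and 8.39 ± 1.55 CPM, and the fat list was not called (camera adjusted p = 0.310). Without either control, none of the fat genes passed edgeR's test. The Cfd call was also lost without U0126 replicate 1 (edgeR adjusted p = 0.150, in a range of 0.0276 to 0.248), and in alternatives that kept all 4 libraries, DESeq2 among them, and that of Dgat2 with library totals alone, among others, and without U0126 replicate 2 (edgeR adjusted p = 0.0552, in a range of 0.00353 to 0.308).

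Matrix genes divided by member rather than moving together. Of 31 collagen and elastic matrix genes, 9 rose, 5 fell and 17 did not pass. Eln, tropoelastin (chromosome 12, 24978483 to 25021863, rn6), rose 5.90-fold from 989 ± 91.7 to 5840 ± 916 CPM. The proteoglycan versican (Vcan) fell 2.48-fold and Col15a1 2.44-fold. Fbln1, Loxl3 and Col6a3, named after their values were seen, also fell. The list was not called (camera adjusted p = 0.216), except without U0126 replicate 1, where it was higher (0.0418), and 10 rose and 5 fell when adjusted over the list alone. Without U0126 replicate 2, 11 fell, and without either control, 3. Of 22 matrix proteases and inhibitors, 5 rose and 7 fell, or 5 and 10 adjusted over the list alone. Mmp2, gelatinase A, rose 2.95-fold from 707 ± 42.2 to 2088 ± 205 CPM, and the inhibitor Timp3 2.36-fold. Mmp14, Timp2 and Serpine2, named after their values were seen, also rose. This list was not called either (camera adjusted p = 0.310), except without control replicate 2, where it was lower (0.00879). Without control replicate 1 it held 3 higher and 3 lower genes, and without control replicate 2, 2 higher and 6 lower.

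Contractile and SRF-YAP genes were lower. Of 20 tested, 16 fell, 1 rose and 3 did not pass, also when adjusted over the list alone. Actg2, smooth muscle gamma actin, fell 6.44-fold, calponin 1 (Cnn1) 2.89-fold from 438 ± 3.99 to 152 ± 33.5 CPM, and tropomyosin 1 (Tpm1) 1.87-fold. The riser was Ctgf, named after its values were seen, at 10640 ± 337 and 13520 ± 292 CPM, which did not pass with library totals alone or without either control or U0126 replicate 2. The list was lower as a set (camera adjusted p = 6.67e-09; adjusted p = 0.322 with an estimated correlation). The fallen members numbered 11 without either control, and the log2 fold change of Actg2 went from -2.69 to -3.27 without U0126 replicate 2. Of 14 mesenchymal stem cell markers, 6 fell and 1 rose, or 7 and 3 adjusted over the list alone. Nes (nestin) fell 9.19-fold, Thy1 1.66-fold from 1502 ± 104 to 904 ± 1.78 CPM, and Alcam 1.93-fold. The riser was Nt5e, named after its values were seen (2.06-fold). The set test missed its threshold (camera adjusted p = 0.0553) but passed, as lower, in 5 of 13 alternatives, with the lowest at 0.0299 and the highest at 0.170; without control replicate 1 it was 0.0492. The risers numbered 2 and 3 without U0126 replicate 1 and 2.

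Markers of cell types other than TSPCs moved alongside these groups, at low levels in most cases. Of 6 tested skeletal muscle markers, 3 fell and 1 rose, or 3 and 2 adjusted over the list alone. Myod1, the myoblast determination factor, went from 2.00 ± 0.166 to 0.160 ± 0.109 CPM, Cdh15 from 2.20 ± 0.246 to 0.619 ± 0.0940 CPM and Acta1, skeletal actin, from 201.5 ± 17.3 to 101.4 ± 29.3 CPM. Tnnt3, named after its values were seen, rose 2.68-fold, and did not pass without either control. Without U0126 replicate 1 the log2 fold change of Myod1 went from -3.61 to -4.54. The Cdh15 call was lost without either control (edgeR adjusted p = 0.118 and 0.0802), and that of Acta1 without control replicate 2 (0.0856). Of 6 pericyte markers, 3 rose and 1 fell, also adjusted over the list alone. The potassium channel subunits Kcnj8 (0.277 ± 0.00119 to 5.88 ± 2.46 CPM) and Abcc9 (5.81 ± 0.0250 to 24.6 ± 6.11 CPM) rose, as did Notch3, named after its values were seen (1.89-fold), and Cox4i2 fell 2.54-fold. The Notch3 call was lost without control replicate 1. Of 5 endothelial markers, Erg rose and Flt1 fell (1.62 ± 0.345 to 0.322 ± 0.104 CPM), also adjusted over the list alone, the latter lost without either control (edgeR adjusted p = 0.139 and 0.0695). Of 6 leukocyte markers, 2 fell, also adjusted over the list alone. Cd74, the invariant chain, went from 3.48 ± 1.15 to 0.576 ± 0.591 CPM, and Adgre1, a macrophage receptor, from 39 counts over the controls to 2 over the U0126 libraries (ratio 0.0575, 95% exact Poisson interval 0.00673 to 0.222). Both calls were lost without control replicate 1 (edgeR adjusted p = 0.0828 for Cd74 and 0.227 for Adgre1) and control replicate 2 (0.212 and 0.134), and that of Adgre1 also without U0126 replicate 2 (0.0674) and in alternatives that kept all 4 libraries. With U0126 replicate 1 left out, 0 counts of Adgre1 remained in that group, and with U0126 replicate 2 left out its log2 fold change was -3.10 against -3.98. The log2 fold change of Cd74 went from -2.60 to -1.81 without U0126 replicate 1 and to -4.45 without U0126 replicate 2. The Schwann cell and epithelial list held 2 tested members, and both rose, also adjusted over the list alone. S100b went from 9.94 ± 3.92 to 32.8 ± 11.6 CPM, a call lost without control replicate 2 (edgeR adjusted p = 0.0594, down to 1.41e-07 over the other alternatives). The list held 1 riser without control replicate 1 or U0126 replicate 1. As sets, the pericyte list (camera adjusted p = 0.0486; adjusted p = 0.322 with an estimated correlation) and the Schwann cell and epithelial list (0.0499; adjusted p = 0.408 with an estimated correlation) were at the threshold. Neither held in every alternative: the pericyte call was lost without control replicate 1 (camera adjusted p = 0.125), with no filter and with the stricter one (0.221 and 0.404), with limma-voom (0.313) and with the length trend removed (0.0577). The Schwann cell and epithelial call was lost without U0126 replicate 1 (camera adjusted p = 0.116), under the stricter filter (0.148), with limma-voom (0.0548) and with the length trend removed (0.0577). The muscle (camera adjusted p = 0.140), leukocyte (0.0835) and endothelial (0.707) lists were not called, and in the last the median log2 fold change was negative while the mean and the test were positive. The leukocyte list passed, as lower, in 3 of 13 alternatives, among them limma-voom (camera adjusted p = 0.0329) and without control replicate 2 (0.0274), in a range up to 0.856. The endothelial list passed, as higher, without U0126 replicate 2 (camera adjusted p = 0.0210).

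Targets of the aryl hydrocarbon receptor, the sensor of planar aromatic compounds, were higher with U0126. Of 7 tested, 6 rose, 0 fell and 1 did not pass, also when adjusted over the list alone. Cyp1b1, a cytochrome P450 induced by the receptor (chromosome 6, 2307808 to 2316722, rn6), rose 4.16-fold from 689 ± 10.6 to 2867 ± 212 CPM. Nqo1, a quinone reductase, rose 4.12-fold from 299.8 ± 9.40 to 1234 ± 106 CPM. Ahrr, the receptor's repressor, rose 5.90-fold. Tiparp and Aldh3a1 rose too, the latter from 8 and 0 counts in the controls to 657 and 311 with U0126. With a mean log2 CPM of 2.70, Aldh3a1 lay below the cut used for the strongest rises. Gsta2, named like Tiparp and Aldh3a1 after its values were seen, was at 0.398 ± 0.0432 and 0.601 ± 0.343 CPM. Cyp1a1 had 0 counts in both controls and 71 and 49 with U0126, at least 44.9-fold higher. The list was higher as a set (camera adjusted p = 8.42e-21; adjusted p = 0.322 with an estimated correlation). The same count of 6 was found without any one library.

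Inflammatory mediators were lower for a subset. Of 24 tested, 8 fell, 1 rose and 15 did not pass, and 9 fell and 1 rose adjusted over the list alone. Il1a, interleukin 1 alpha, fell 11.9-fold from 6.51 ± 1.92 to 0.546 ± 0.400 CPM, in addition to Cxcl2. Its log2 fold change went from -3.58 to -2.96 without U0126 replicate 1 and to -4.62 without U0126 replicate 2. Cxcl12, a stromal chemokine, fell 2.52-fold from 537 ± 57.0 to 213 ± 58.2 CPM. The riser was Vcam1, named after its values were seen, at 5.90 ± 0.105 and 11.8 ± 1.76 CPM, which did not pass without either control. The list was lower as a set (camera adjusted p = 0.00108; adjusted p = 0.470 with an estimated correlation). The fallen members were 4 without control replicate 1 and 20 without U0126 replicate 2, and the risers 3 and 2 without U0126 replicate 1 and 2. Of 17 interferon response genes, 6 fell and 1 rose, or 9 and 1 adjusted over the list alone. Ifi27 fell 2.24-fold, from 212.5 ± 22.6 to 95.0 ± 13.1 CPM. Usp18 fell 6.57-fold, and Mx2, an antiviral GTPase, went from 104 counts over the controls to 0, at least 30.9-fold lower. The list was lower as a set (camera adjusted p = 0.00773; adjusted p = 0.322 with an estimated correlation). Without control replicate 1, 2 members fell and the Usp18 call was lost (edgeR adjusted p = 0.0586), and without control replicate 2, 4 fell. Under the stricter filter, which leaves 2 fallen members, the list was not called (camera adjusted p = 0.436).

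Lysosome and autophagy genes were higher by modest amounts. Of 23 tested, 14 rose, 0 fell and 9 did not pass, and 18 rose and 1 fell adjusted over the list alone. The cathepsins Ctsb and Ctsd rose 1.70-fold and 1.65-fold, and Gabarapl1, an autophagosome protein, 1.54-fold (camera adjusted p = 2.48e-06 for the list; adjusted p = 0.322 with an estimated correlation). Without control replicate 1, 4 members rose, and without control replicate 2, 2 did, with Gabarapl1 lost (edgeR adjusted p = 0.0913). Of 22 hypoxia and glycolysis genes, 12 fell and 1 rose, or 14 and 1 adjusted over the list alone. Enolase (Eno1) and hexokinase 2 (Hk2) each fell 1.83-fold, and Car9, carbonic anhydrase 9, rose 3.71-fold (camera adjusted p = 0.00251 for the list, lower; adjusted p = 0.470 with an estimated correlation). The fallen members were 3 without control replicate 1 and 6 without control replicate 2, and 3 rose without U0126 replicate 1. Of 21 cholesterol synthesis genes, 7 fell and 0 rose, or 9 and 0 adjusted over the list alone. Insig1, a regulator of sterol synthesis, fell 1.62-fold (camera adjusted p = 0.00658 for the list; adjusted p = 0.441 with an estimated correlation). The fallen members were 4 and 2 without control replicate 1 and 2, the latter without Insig1 (edgeR adjusted p = 0.0744), and 12 without U0126 replicate 2. Of 20 integrated stress and unfolded protein genes, 6 rose and 4 fell, or 8 and 4 adjusted over the list alone. Ddit4 rose 3.29-fold, Trib3 3.17-fold and Herpud1 1.65-fold; the list was not called (camera adjusted p = 0.138), with a negative median and a positive mean and test. Sdf2l1, Pdia4, Phgdh and Hsp90b1, named after their values were seen, fell. It was called, as higher, without U0126 replicate 1 (camera adjusted p = 0.0105), and held 3 and 4 risers without control replicate 1 and 2, with 1 fallen member each, and 6 fallen without U0126 replicate 2.

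Among 21 BMP and TGF-beta response genes, 8 fell and 3 rose, or 12 and 5 adjusted over the list alone. Tgfb3 fell 2.36-fold from 1442 ± 116 to 612 ± 46.7 CPM and Inhba, an activin subunit, 2.05-fold. Pmepa1 rose 2.03-fold (camera adjusted p = 0.0443 for the list, lower; adjusted p = 0.322 with an estimated correlation). Fst and Bambi, named after their values were seen, rose as well. Without either control, 1 rose, and 4 and 5 fell; the set was not called without control replicate 1 (camera adjusted p = 0.0661) or U0126 replicate 2 (0.0657). Of 12 Wnt response genes, 4 rose and 1 fell, also adjusted over the list alone. Nkd1 rose 12.1-fold and Wisp1 1.78-fold, while Wnt5a fell 1.95-fold (camera adjusted p = 0.0486 for the list, higher; adjusted p = 0.322 with an estimated correlation). Dkk3 and Nkd2, named after their values were seen, rose as well. The set call held in 5 of 13 alternatives and was lost without any one library (camera adjusted p = 0.104, 0.0718, 0.0734 and 0.133 without control replicate 1 and 2 and U0126 replicate 1 and 2). Without either control, 2 Wnt genes rose, and the Wnt5a call was lost without control replicate 2 (edgeR adjusted p = 0.0588).

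**Figure D3:**
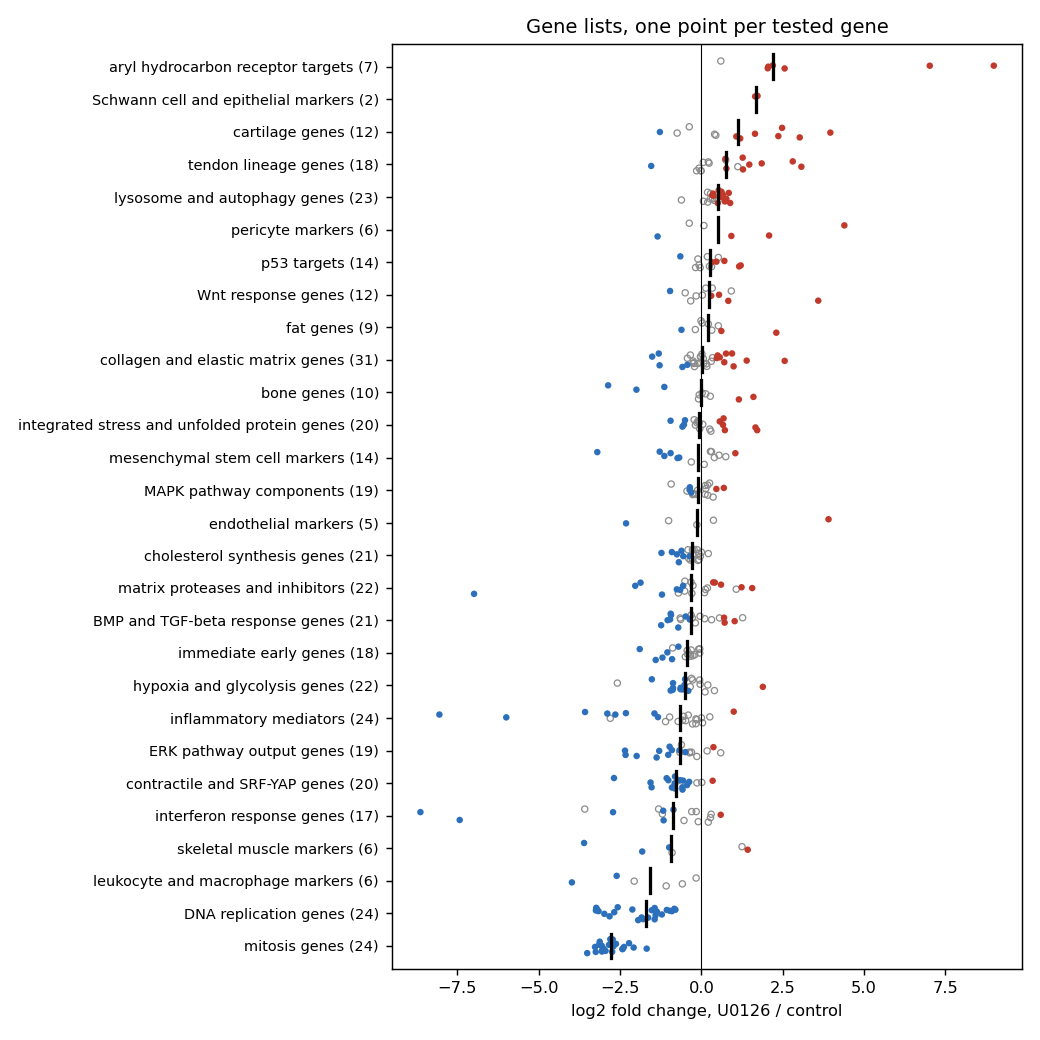
Log2 fold change of U0126 over control (x axis) for each tested member of the 28 gene lists, with the number tested in brackets. Filled red points were higher and filled blue points lower past the test, open points did not pass, and the black bar is the list's median, which was -2.79 for mitosis genes and 2.20 for aryl hydrocarbon receptor targets, with Cyp1a1 at its fitted value or at its bound.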

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

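The tests without the mitochondrially encoded genes and with the length trend removed were chosen after the data had been seen. No library can be said to come from a shared animal or day, and same-numbered libraries did not deviate together (correlation -0.03). With the replicate number as a block, 2371 genes changed, 2302 of them among the 2792; Cfd, Dgat2, Map2k1, Mapk3, Hras, Adgre1 and Myc did not pass there, the Wnt list was not called, and the stem cell marker and leukocyte lists were. The number of changed genes lay between 2371 and 2937 over the alternatives that kept all 4 libraries, which were RLE factors, library totals, both filters, DESeq2, limma-voom, the block, and the 2 added later. The count of genes changed at least 2-fold fell to 725 under the stricter filter, which tested 10279 genes. Leaving out 1 library gave between 899 and 4644 changed genes, 295 to 2138 higher, 604 to 2506 lower, 695 to 1456 changed at least 2-fold, and 15 to 19 lists called against 18. The counts were 913 and 899 without control replicate 1 and 2, where the spread rests on the U0126 pair and the lone control is assumed to vary like it, and 4644 without U0126 replicate 2, where it rests on the closer control pair. With an estimated inter-gene correlation, 0 lists were called by camera, 4 had an unadjusted p under 0.05, and fry called 16. The share of calls that were higher was 42.3%, 33.9% with library totals alone and 48.3% with the length trend removed. Of 102 named genes past the threshold, 11 were not tested under the stricter filter. Of the other 91, 71 passed in all 13 alternatives that refit the genes and 86 in the planned ones that kept all 4 libraries; none of the 102 changed direction where tested. In all, 42 of the 63 losses came from leaving out a control. With library totals alone, the median of the collagen and elastic matrix list turned from 0.02 to -0.04, and with the length trend removed that of the bone list from -0.02 to 0.01; neither list was called under that setting. Depth limited genes such as Tnmd, with 7 and 2 counts per group.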

Other observations

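The gene families, single genes and pathways below that the report does not name, and the tests of paralog reads and of leukocytes, were chosen after the results had been seen, while the tests of NRF2 targets, length bias and nuclear oxidative phosphorylation genes were set before their values were looked at, except that Slc7a11, 1 of the 9 NRF2 targets, had already been seen. Of 19 tested integrin subunits, 8 fell, 0 rose and 11 did not pass by edgeR, with the fibronectin receptor subunit Itga5 going from 403 ± 23.5 to 139 ± 39.7 CPM, Itga3 from 130 ± 18.5 to 24.5 ± 10.2 CPM and the shared beta subunit Itgb1 from 2730 ± 266 to 1703 ± 42.6 CPM. Of 10 S100 calcium-binding proteins, 4 fell, among them S100a4 (2.50-fold) and S100a6 (2.17-fold), and S100b rose. Of 6 IGF binding proteins, 4 rose and Igfbp6 fell (41.9 ± 0.631 to 26.2 ± 2.21 CPM), with Igfbp2 at 465 ± 22.5 and 2175 ± 130 CPM; with library totals alone 3 rose. Receptor partners for calcitonin-family ligands moved apart: Ramp1 went from 5.70 ± 0.815 to 49.9 ± 12.3 CPM while Ramp3 fell 57.5-fold and Ramp2 did not pass. Among 12 ADAMTS proteases, 5 rose and 2 fell, and the prostaglandin E receptors Ptger3 and Ptger4 rose while Ptger1 did not pass. With RLE factors or library totals the counts of higher and lower members were the same for each of these families, apart from that of the IGF binding proteins. The family counts were not taken in the other alternatives, so they may not hold with a library left out.

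Among abundant genes, at a mean log2 CPM of at least 7, the scaffold protein Akap12 fell most, from 758 ± 98.7 to 73.0 ± 10.6 CPM, and the water channel Aqp1 went from 3379 ± 49.4 to 930.6 ± 91.3 CPM. Among the rises, Igfbp3 had the highest log2 fold change (3.61 ± 0.21 SE), close to that of Tnn, tenascin N (3.58 ± 0.14 SE). Without U0126 replicate 1 that of Igfbp3 was 3.265. Tnn went from 462 ± 8.28 to 5511 ± 965 CPM and Cilp, cartilage intermediate layer protein, from 81.9 ± 11 to 497 ± 29.6 CPM. Igfbp3 was at 40.7 CPM in the controls and 498 CPM with U0126. Igfbp3 and Cilp passed the cut through the U0126 libraries, and Akap12 through the controls. Tnn thus rose in the same libraries in which Tnc of the same family fell. Of 257 KEGG pathways in the deposited annotation with 15 to 250 tested genes, camera called 31, of which 30 were lower and 1, Lysosome, was higher (18 of 75 genes higher, 4 lower, adjusted p = 0.00637). With an estimated correlation the smallest adjusted p over the pathways was 0.881. DNA replication (19 of 29 lower), Cell cycle (35 of 91 lower) and Regulation of actin cytoskeleton (36 of 112 lower) were among those called as lower.

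Aryl hydrocarbon receptor targets rose with U0126. Reads shared between Cyp1 paralogs cannot account for the rise outside the Cyp1 family, where the 5 tested members had a median log2 fold change of 2.20. Most of these members were already known to have risen. Their values do not show whether Cyp1a1 and Cyp1b1 share reads. A general NRF2 stress response, which also induces Nqo1, is argued against as the whole source: 9 NRF2 targets other than Nqo1 had a median of 0.221 (quartiles -0.0501 and 0.497), although 4 of them rose, Osgin1 by 2.69. An action of the compound on the receptor itself may account for the rise, and so may a consequence of ERK inhibition. With 1 compound and no second MEK inhibitor the design does not separate these, and neither was tested.

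Of 34 tested mitochondrially encoded genes, 19 rose with U0126, 0 fell and 15 did not pass (median log2 fold change 0.67 with quartiles 0.35 and 0.92). All tested genes with an Mt- symbol, which encode oxidative phosphorylation subunits, rose. Their log2 fold changes ran from 0.467 for Mt-nd4l to 0.961 for Mt-cox3. The 15 that did not pass all carried placeholder names. Gene length bias is argued against: fold changes barely followed effective length across genes (Spearman rho 0.04, across 13670 genes, which are not independent replicates), and the mitochondrial median was 0.681 once the trend was removed. A rise of the whole oxidative phosphorylation programme is also argued against, since 99 nuclear-encoded members had a median of -0.0593 (quartiles -0.182 and 0.0855). Leaving the mitochondrial genes out gave 2748 changed genes, of which 2740 were among the 2792. Differences in RNA quality or cell state between the cultures may remain as sources and were not tested.

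Ccl22, Cxcl2, Il1a and Csf2, which immune cells among others can make, all fell, as did the leukocyte markers Cd74 and Adgre1. Loss of leukocytes present in the control cultures could give such a fall, but 5 pan-leukocyte transcripts (Ptprc, Tyrobp, Fcer1g, Laptm5 and Cd53) summed to 0.414 CPM in the controls, 0.787% of the level of Ccl22. The 5 were picked after values had been seen and leave out Cd74 and Adgre1, at 3.48 and 0.474 CPM in the controls. The sum thus depends on the markers chosen. It shows only that these 5 markers were scarce, with Ptprc and Tyrobp at 0 counts in every library and the others at no more than 13. How much Ccl22 a leukocyte holds per marker transcript is not known here, so the sum does not settle the source of Ccl22. The control libraries held 1600 and 2718 counts of Ccl22. Regulation within the TSPCs, or in another non-leukocyte cell of the culture, stays open as a hypothesis and was not tested.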
